A study of Mus musculus with 6 samples.

How the data were processed

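The deposited series holds small RNA sequencing of liver-infiltrating immune cells from wildtype female C57BL/6J mice aged 10 weeks, which the labels call 2 biological replicates in each of 3 groups. Vehicle mice received DMSO in corn oil and had no disease. ConA+Vehicle mice received concanavalin A (ConA), a plant lectin that activates T cells and causes an immune hepatitis in mice, at 12.5 mg/kg into the retro-orbital vein. ConA+D8THC mice received in addition delta-8-tetrahydrocannabinol (D8THC), a cannabinoid, at 20 mg/kg in 100 µL into the peritoneum, 15 to 18 h before ConA and again 30 min after it. Per the labels, livers were dissociated with a Miltenyi kit and RNA was isolated with a miRNeasy kit. The labels also name QIAseq miRNA libraries and a NextSeq 550 sequencer. The hour of tissue collection, the number of mice behind each library, any litter, batch or date, and the yield of cells are not given in the sources used here.

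The deposited table holds raw counts per mature mouse miRNA, whole numbers without normalization, which the authors made by alignment and counting in QIAGEN's GeneGlobe portal with genome build mm10. The aligner, its version, the miRNA annotation release, the handling of reads that match several miRNAs, and whether reads or unique molecular identifiers were counted are not given in the sources used here. The table lists 1960 miRNAs, of which 806 had a count in any library. Library totals ran from 322764 to 1172389 counts, so that 3 counts correspond to 2.56 to 9.29 CPM, the usual counts scaled to library size. A group with no count is given with that floor of 3 counts over the group, and its fold as "at least". Floors and intervals cover counting error only. Near-identical miRNAs (miR-17-5p and miR-106a-5p, miR-20a-5p and miR-20b-5p, the let-7 members, miR-199a-3p and miR-199b-3p) can share reads.

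Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plotted in Python 3.11.15 with matplotlib 3.10.9. filterByExpr by group kept 297 miRNAs, which held at least 99.9% of each library's counts. TMM factors, a group design over all 6 libraries (3 residual degrees of freedom), glmQLFit with robust estimation and glmQLFTest gave the main test. The 3 contrasts of group means were ConA+Vehicle against Vehicle, ConA+D8THC against ConA+Vehicle, and ConA+D8THC against Vehicle. P-values were adjusted by Benjamini-Hochberg over the 297 miRNAs of a contrast, and a miRNA was called at an adjusted p under 0.05. Adjusted p-values of single miRNAs are edgeR quasi-likelihood values unless another tool is named. Errors of log2 fold changes are approximate standard errors, computed as the absolute log2 fold change over the square root of the test's F. CPM values use TMM-scaled library sizes and are means with SD over 2 libraries; shares of counts are percentages of a library's total count. A single value compared between groups of 2 has a smallest exact two-sided permutation p of 0.333, so shares are given without a test.

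Before the data were examined, 16 miRNA lists were fixed: inflammation-induced, T cell activation-induced, resting lymphocyte, miR-17~92 and paralogous clusters, let-7 family, miR-30 family, p53-induced miR-34 family, Dlk1-Dio3 imprinted cluster, and markers of myeloid, lymphocyte, pan-haematopoietic, erythroid, hepatocyte, endothelial, stellate cell and fibroblast, and bile duct epithelium. The 12 lists with at least 3 tested members went to limma's camera on voom values (preset correlation 0.01, then with the correlation estimated) and to fry, adjusted over the lists of a contrast. Members are also counted as called over all miRNAs and adjusted over the list alone. The rule for naming miRNAs was fixed at the same time. It took, per contrast, the 10 largest called changes in each direction with a mean of at least 10 CPM and separate libraries, or the 5 smallest p-values in a direction with too few. It added the 4 most abundant members of each list, 8 fixed miRNAs, the opposite calls and the 5 most abundant miRNAs. Others are named as chosen after their values were seen.

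Opposite calls are miRNAs called in both ConA+Vehicle against Vehicle and ConA+D8THC against ConA+Vehicle with opposite signs. Because these contrasts share the ConA+Vehicle libraries, the count is given with the number expected from independent calls and with that from 100 simulated data sets of unchanged groups with the same sharing. Positions are those of the hairpin genes in GENCODE M21, or RefSeq GRCm38.p6 where GENCODE has none, in build mm10. Hairpins were matched by gene name, and 289 of the 297 tested miRNAs had a match.

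The procedure was tested on simulated data: negative binomial draws at the spread of these libraries, with 200 of 806 miRNAs changed, 20 draws. Among changed miRNAs that passed the filter, it recovered 34.2%, 32.5% and 38.5% of 2-fold changes in the 3 contrasts in their order. For 4-fold changes this was 84.7%, 80.8% and 86.6%. On average 296, 302 and 302 of the 806 passed, and changed miRNAs that did not pass are not counted. The share of false calls was 3.62%, 4.51% and 3.01%. In a further draw with the miR-17~92 list shifted 2-fold, camera with the preset correlation called 1 of 12 lists, the shifted one. The shifted list also passed with the estimated correlation. Its members were drawn independently, while their estimated correlation in ConA+Vehicle against Vehicle was 0.766, so the draw does not test camera under such correlation.

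Alternatives were RLE size factors, library totals alone, upper-quartile factors, erythroid and hepatocyte markers left out, no filter, a filter of 10 CPM in 2 libraries, a fit of 2 against 2 libraries, the replicate number as a block, each library left out in turn, DESeq2's Wald test, limma-voom, the quasi-likelihood test without robust estimation, an FDR of 0.1, and a 2-fold minimum. Added after the data were seen were thinning of every library to the smallest total (20 draws, median), leaving out pancreas-enriched miRNAs, and leaving out 8 entries listed as fragment-like. Of these, 2 overlap small nucleolar RNA genes, and the other 6 were picked after their calls were seen as possible fragments of longer RNAs, which was not tested. Ranges of adjusted p for single miRNAs cover the refits, not thinning, the FDR of 0.1 or the 2-fold minimum. All 6 libraries were used and none was set aside. miRNA targets and the raw reads, which the submitters state are lost, were not analysed here. The spread of the 6 hepatocyte log2 fold changes was measured as Cochran's Q and read against 100 negative binomial draws at the fitted means and dispersions, with 1 common shift for the 6 and the model refitted to each draw. This simulation was chosen after a large-sample form of the test had been seen.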

Results

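Mature miRNAs were counted in immune cells isolated from the livers of mice in 3 groups, with 2 libraries per group: Vehicle, ConA+Vehicle and ConA+D8THC. Total counts were 753887 and 1172389 in Vehicle replicates 1 and 2, 381274 and 322764 in ConA+Vehicle replicates 1 and 2, and 913285 and 690713 in ConA+D8THC replicates 1 and 2. These libraries held a count for 539, 581, 488, 446, 575 and 553 miRNAs, in the same order. The first principal component of the 297 tested miRNAs held 62.7% of the variance and set the Vehicle libraries (-11.8 and -14.4) apart from ConA+Vehicle (9.34 and 9.19) and ConA+D8THC (4.22 and 3.41). The second held 18.2% and set ConA+D8THC (-8.61 and -5.03) apart from ConA+Vehicle (5.16 and 5.24). Pearson's r between the replicates of a group, across the tested miRNAs on the log2 scale, was 0.985 in Vehicle, 0.979 in ConA+Vehicle and 0.983 in ConA+D8THC; miRNAs are not independent replicates.

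Markers of several cell types shared each library. The endothelial markers miR-126a-3p and miR-126a-5p took 33.4% ± 1.04 (SD, n = 2) of all counts in Vehicle, 13.0% ± 0.310 in ConA+Vehicle and 23.7% ± 4.18 in ConA+D8THC. Hepatocyte markers took 11.1% ± 3.91, 18.4% ± 1.90 and 6.17% ± 1.39 in the same order of groups. Pan-haematopoietic markers, the arms of miR-142a, took 4.92% ± 3.38, 9.66% ± 0.886 and 9.45% ± 2.45; the Vehicle replicates differed from each other, with 7.31% in replicate 1 and 2.53% in replicate 2. Myeloid markers took 1.32% ± 0.149, 3.34% ± 0.0614 and 2.44% ± 0.488, and lymphocyte markers 0.699% ± 0.175, 1.00% ± 0.172 and 0.853% ± 0.288. Erythroid markers took 0.0732% ± 0.0422, 0.133% ± 0.0668 and 0.0498% ± 0.00839. Stellate cell and fibroblast markers (1.30%, 1.02% and 1.00%) and bile duct epithelium markers (0.449%, 0.455% and 0.433%) differed less between the groups. The most abundant miRNA was miR-126a-3p in the Vehicle and ConA+D8THC libraries and the hepatocyte miRNA miR-122-5p in both ConA+Vehicle libraries.

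**Figure D1:**
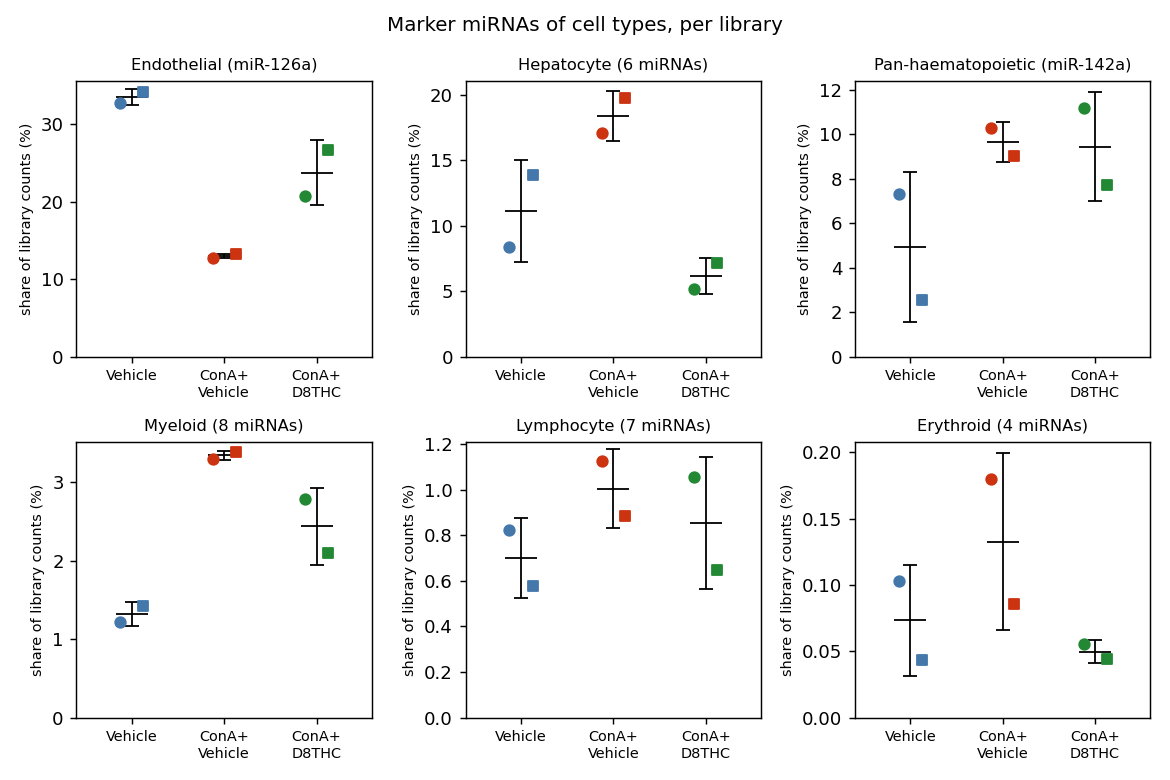
Share of each library's counts (percent) taken by the markers of 6 cell types, with 1 point per library (circle, replicate 1; square, replicate 2) and the group mean with its SD (n = 2) as lines. Endothelial markers averaged 33.4% in Vehicle, 13.0% in ConA+Vehicle and 23.7% in ConA+D8THC, and hepatocyte markers 11.1%, 18.4% and 6.17%.

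ConA+Vehicle was compared with Vehicle to ask which miRNAs differ in the liver immune cells of mice with ConA hepatitis. miR-223-3p, a miRNA of neutrophils and other myeloid cells (hairpin at chromosome X, 96242817 to 96242926), rose from 3512 ± 111 to 28525 ± 3459 CPM (SD, n = 2), which was 8.12-fold (log2 3.02 ± 0.25, adjusted p = 4.43e-05). miR-155-5p, induced on activation of lymphocytes and macrophages and encoded in an exon of Mir155hg (chromosome 16, 84714140 to 84714204), rose 6.77-fold from 1301 ± 297 to 8807 ± 450 CPM (adjusted p = 5.32e-05). The endothelial miR-126a-3p, whose hairpin lies in Egfl7 (chromosome 2, 26591357 to 26591429), fell from 263518 ± 30228 to 93790 ± 8054 CPM and was 2.81-fold lower (adjusted p = 0.000921). miR-511-3p, from an intron of the macrophage mannose receptor gene Mrc1 (chromosome 2, 14261003 to 14261081), was 8.55-fold lower, at 13.3 ± 4.65 CPM against 112 ± 40.0 (adjusted p = 0.000638).

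Among the 297 miRNAs tested, 109 were called, 59 higher and 50 lower in ConA+Vehicle; the libraries of the 2 groups did not overlap for any of these 109. Of all 297, 200 had groups that did not overlap, against 33.3% expected by chance. Without ConA+Vehicle replicate 1, 67 miRNAs were called, 64 of them among the 109. The endothelial share of counts went from 33.4% to 13.0% beside the lists that follow, and the myeloid share went from 1.32% to 3.34%.

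The inflammation-induced list rose (camera, adjusted p = 0.0198; adjusted p = 0.477 with an estimated correlation). Of its 11 tested members, 7 rose, 0 fell and 4 were not called; adjusted over the list alone, 8 were higher and 1 lower. Besides miR-155-5p these included miR-21a-5p, an abundant inducible miRNA that rose 2.90-fold to 82363 ± 4688 CPM, its passenger strand miR-21a-3p at 7.74-fold, and miR-147-3p, a miRNA induced in macrophages by Toll-like receptor ligands, at 11.6-fold. miR-146a-5p, an NF-kappaB target and brake on inflammatory signalling, did not pass in the main test, with 22426 ± 3194 CPM in Vehicle and 15325 ± 2544 in ConA+Vehicle (adjusted p = 0.0856). It was called lower by DESeq2 (log2 -0.65, adjusted p = 0.0461), with the replicate block (0.0191) and with fragment-like entries left out (0.0470). Without Vehicle replicate 1 the increase of miR-21a-5p was 4.97-fold.

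The proliferation-linked miR-17~92 cluster and its paralogs rose as a list (camera, adjusted p = 2.43e-06; adjusted p = 0.477 with an estimated correlation). In it, 13 of 14 members rose, over all miRNAs and adjusted over the list alone, and miR-106b-5p, named after its value was seen, was not called (log2 -0.02 ± 0.41). miR-93-5p rose 2.41-fold to 8457 ± 194 CPM, miR-25-3p 2.13-fold to 5229 ± 201 CPM, miR-19b-3p 3.43-fold and miR-20a-5p 3.19-fold. miR-210-3p, a hypoxia-responsive miRNA on the T cell activation list, rose 7.01-fold to 240 ± 2.51 CPM (adjusted p = 0.000379). That list had 3 of 9 members higher and did not pass in camera (adjusted p = 0.112, in a range of 0.0135 to 0.158 over the alternatives). It was higher in fry, a test of a list on its own (adjusted p = 0.00279).

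Marker miRNAs of cell types moved apart. The myeloid list did not pass (camera, adjusted p = 0.151), with 2 members higher, 5 lower and 1 not called. Both arms of miR-223 rose, while both arms of miR-511 and the clustered miR-99b-5p, miR-125a-5p and let-7e-5p fell; miR-125a-5p was 2.70-fold lower and let-7e-5p 2.33-fold lower. The call of miR-99b-5p ended without ConA+Vehicle replicate 1 (adjusted p = 0.0627, in a range of 5.50e-06 to 0.0627). The arm miR-511-5p was not called without Vehicle replicate 2, ConA+Vehicle replicate 1 or ConA+Vehicle replicate 2, nor by DESeq2, limma-voom or library totals, with adjusted p-values from 0.00701 to 0.199. Of the pan-haematopoietic pair, miR-142a-5p rose 2.48-fold (3.93-fold without Vehicle replicate 1). In the main test miR-142a-3p was not called, at 42146 ± 30658 CPM in Vehicle and 75108 ± 731 in ConA+Vehicle (log2 0.83). It was called higher with no filter (adjusted p = 0.0333) and with 2 against 2 libraries (0.0390), and was at log2 1.86 without Vehicle replicate 1. Both arms of miR-126a, the endothelial pair, fell; the call of miR-126a-5p (2.20-fold lower) ended without ConA+Vehicle replicate 1 (adjusted p = 0.0547, in a range of 3.44e-05 to 0.0547).

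Of the 6 hepatocyte miRNAs, 4 rose and 1 fell, and the list did not pass (camera, adjusted p = 0.168; 0.0282 without Vehicle replicate 2, in a range of 0.0282 to 0.535). miR-192-5p rose 2.75-fold from 3644 ± 866 to 10024 ± 2107 CPM (adjusted p = 0.00265). miR-148a-3p rose 2.34-fold, miR-802-5p 2.34-fold and miR-194-5p 1.85-fold. Leaving out Vehicle replicate 1 ended these 3 calls, with adjusted p-values of 0.0927, 0.0898 and 0.0782, the highest over the alternatives run for each; the lowest were 2.28e-07, 0.000426 and 4.11e-05. ConA+Vehicle replicate 1 was needed for miR-802-5p (0.0725 without it) and miR-194-5p (0.0552), and ConA+Vehicle replicate 2 for miR-148a-3p (0.0522) and miR-194-5p (0.0732), whose call also ended with no filter (0.0733). miR-122-5p, the dominant hepatocyte miRNA, was not called in the main test (log2 0.62 ± 0.29, adjusted p = 0.124). It was called higher with the replicate block (adjusted p = 0.00431), and was at log2 1.05 without Vehicle replicate 2. The opposite strand of the same hairpin, miR-122-3p, was 2.28-fold lower (adjusted p = 0.0167), a call that ended without ConA+Vehicle replicate 1 (0.0596) or ConA+Vehicle replicate 2 (0.143, in a range of 0.00228 to 0.143).

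The remaining lists did not pass in camera. The let-7 family had 4 of 10 members lower (adjusted p = 0.0931) and the miR-30 family 3 of 7 (adjusted p = 0.0931). In the latter, miR-30c-5p was 2.40-fold lower at 3680 ± 543 CPM. Both families were lower in fry (adjusted p = 0.0325 and 0.00448). The resting lymphocyte list had 2 members higher and 3 lower of 9 (adjusted p = 0.779; median log2 0.21, mean -0.05). The lymphocyte list had 1 of 6 higher, 0 adjusted over the list alone and 0 in DESeq2 or limma-voom (adjusted p = 0.957; median log2 -0.02, mean 0.07). The 1 was miR-342-3p (adjusted p = 0.0468), 1.65-fold and so under the 2-fold minimum. Its call also ended in 10 of 19 refits, among them without Vehicle replicate 2 (0.0648), ConA+Vehicle replicate 1 (0.0641) or ConA+Vehicle replicate 2 (0.262), in a range of 0.00346 to 0.262. The lymphoid marker miR-150-5p was not called (log2 0.50 ± 0.29). In the stellate cell and fibroblast list 2 of 6 were lower (adjusted p = 0.112; 0.0220 without ConA+Vehicle replicate 1, in a range of 0.00837 to 0.471), with miR-199a-3p 2.22-fold lower. The main edgeR test called 0 of the 4 erythroid miRNAs (adjusted p = 0.210), 1 of which had an unadjusted p under 0.05 and was called by DESeq2 and limma-voom. With no filter, edgeR called miR-144-3p (adjusted p = 0.00256) and miR-144-5p (0.0458) higher, and with the replicate block miR-451a (0.0166). Without Vehicle replicate 1, miR-144-5p was at log2 2.23, miR-451a at 1.47 and miR-486a-5p at 1.09. Of the 5 of bile duct epithelium, the main test called 0 (adjusted p = 0.847, median log2 -0.08, mean 0.04). There 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The single tested member of the miR-34 family (log2 0.28) and the 2 of the Dlk1-Dio3 cluster (-0.48 and 0.19) were not called.

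Outside the lists, miR-139-5p, from an intron of Pde2a, was 4.16-fold lower, falling from 2535 ± 649 to 608 ± 45.9 CPM. miR-10a-5p was 3.08-fold lower, miR-99a-5p 3.06-fold, miR-151-5p 5.03-fold, miR-331-3p 6.07-fold and miR-652-3p 3.29-fold. Among the largest increases were miR-147-5p (log2 5.44, adjusted p = 0.000606) and miR-135a-5p (3.76, 0.00134), both called in 19 of 19 refits. Others belonged to entries sparse in Vehicle or listed as fragment-like. miR-2137 rose from 3.76 ± 3.36 to 1850 ± 290 CPM (log2 8.72 ± 0.96, adjusted p = 0.000568). Its call ended without Vehicle replicate 1 (adjusted p = 0.0836), Vehicle replicate 2 (0.147, log2 10.21) or ConA+Vehicle replicate 2 (0.0594), in a range of 5.21e-76 to 0.147. miR-6236 had no count in Vehicle and 43.9 ± 12.8 CPM in ConA+Vehicle, at least 27.4-fold higher against a floor of 3 counts over the Vehicle group. The hairpin of miR-5121 overlaps the small nucleolar RNA gene Snord33 within Rpl13a (chromosome 7, 45126918 to 45126991). miR-5121 rose 10.6-fold from 42.3 ± 6.52 to 445 ± 12.0 CPM.

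**Figure D2:**
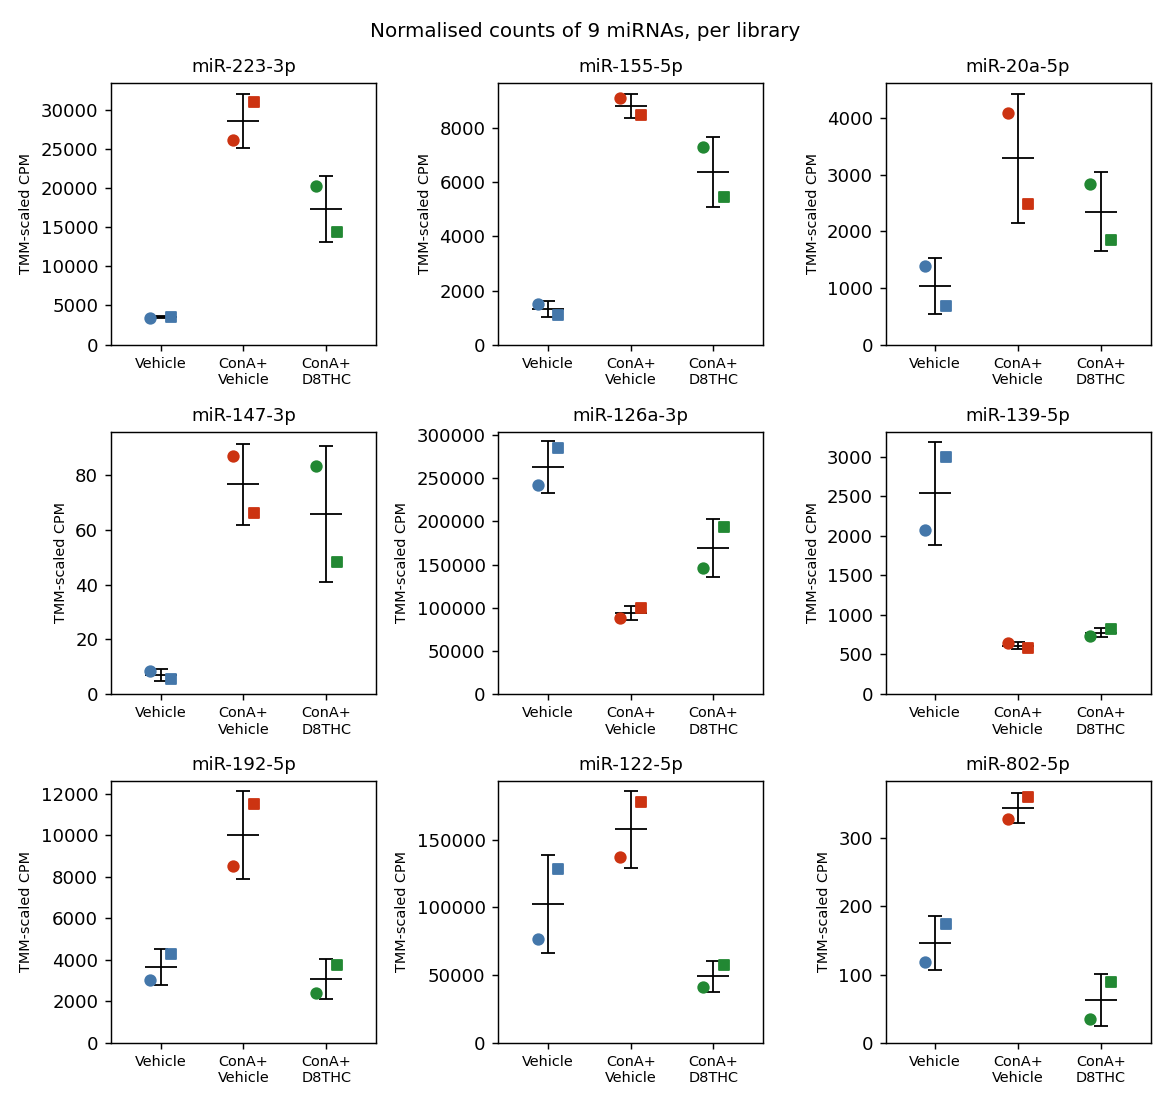
TMM-scaled CPM of 9 miRNAs on linear axes from 0, with 1 point per library (circle, replicate 1; square, replicate 2) and the group mean with its SD (n = 2) as lines. miR-223-3p averaged 3512, 28525 and 17331 CPM and miR-122-5p 102526, 157786 and 49072 CPM in Vehicle, ConA+Vehicle and ConA+D8THC.

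ConA+D8THC was compared with ConA+Vehicle to ask what D8THC changed in mice given ConA. The hepatocyte miRNA miR-122-5p (hairpin at chromosome 18, 65248861 to 65248926) fell from 157786 ± 28457 to 49072 ± 11355 CPM (SD, n = 2) and was 3.22-fold lower (log2 -1.68 ± 0.30, adjusted p = 0.00999). The liver and gut miRNAs miR-192-5p (chromosome 19, 6264844 to 6264932) and miR-194-5p fell with it, by 3.26-fold and 3.46-fold, and miR-802-5p (chromosome 16, 93369720 to 93369816), a hepatocyte miRNA linked to glucose metabolism, was 5.61-fold lower. miR-216a-5p, a miRNA of pancreatic acinar cells (chromosome 11, 28757012 to 28757083), was at 26.5 ± 4.77 CPM in ConA+Vehicle and 25.7 ± 7.06 in Vehicle and had no count in ConA+D8THC, at least 14.4-fold lower (adjusted p = 0.00538). miR-5121 fell from 445 ± 12.0 to 57.1 ± 34 CPM, 7.92-fold lower (adjusted p = 0.00399).

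Of the 297 miRNAs, 11 were called, 0 higher and 11 lower in ConA+D8THC by the edgeR test. At an unadjusted p under 0.05 there were 19 higher and 37 lower; DESeq2 called 5 higher and 12 lower, and limma-voom 1 higher and 13 lower. The other members of the 11 were miR-217-5p, miR-375-3p, miR-6538, miR-3535 and miR-5126, of which miR-217-5p and miR-5126 were chosen after their values were seen. The 11 thus held 4 hepatocyte markers, 4 entries listed as fragment-like, and the pancreas-enriched miR-216a-5p, miR-217-5p and miR-375-3p. The edgeR test called 0 members of the myeloid, lymphocyte and pan-haematopoietic lists, and DESeq2 called 1 myeloid miRNA. The call of miR-217-5p ended without ConA+Vehicle replicate 1 (adjusted p = 0.0676) or ConA+D8THC replicate 1 (0.0661), in a range of 0.00129 to 0.0676. That of miR-5126 ended without ConA+Vehicle replicate 1 (0.213), ConA+Vehicle replicate 2 (0.0950) or ConA+D8THC replicate 2 (0.116), in DESeq2 (0.159) and with pancreas-enriched miRNAs left out (0.0575), in a range of 0.000965 to 0.213. The islet miRNA miR-375-3p was 6.84-fold lower, a call that ended without ConA+Vehicle replicate 1 (log2 -1.94, adjusted p = 0.338) and in DESeq2 (0.0507), in a range of 0.000101 to 0.338. The count moved by over 1.5 times with several settings: 44 with the replicate block (12 higher and 32 lower), 34 without Vehicle replicate 1, 40 without Vehicle replicate 2, 17 without ConA+Vehicle replicate 2, 17 without ConA+D8THC replicate 1, 24 without ConA+D8THC replicate 2, 17 with upper-quartile factors, 19 with no filter, 18 with 2 against 2 libraries, 17 in DESeq2, 26 at an FDR of 0.1 and 5 with pancreas-enriched miRNAs left out. These sets held 9 or more of the 11, except the last, whose 5 were all among them.

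The hepatocyte list fell (camera, adjusted p = 1.15e-07; adjusted p = 0.757 with an estimated correlation): 4 of 6 members were called lower over all miRNAs and all 6 adjusted over the list alone. The share of counts from hepatocyte markers went from 18.4% to 6.17% and that from endothelial markers from 13.0% to 23.7%. The members that did not pass over all miRNAs were miR-148a-3p (log2 -1.21 ± 0.34) and miR-122-3p (log2 -1.43 ± 0.36). Without ConA+D8THC replicate 2, miR-802-5p was at log2 -3.26 and miR-5121 at -3.72. The erythroid list also fell (camera, adjusted p = 0.0252; adjusted p = 0.865 with an estimated correlation), with 0 of 4 members called over all miRNAs (4 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom) and 4 lower adjusted over the list alone. Its most abundant member, miR-451a, was at 589 ± 379 CPM in ConA+Vehicle and 152 ± 14.0 in ConA+D8THC (adjusted p = 0.0955). Without ConA+Vehicle replicate 1 the erythroid list did not pass (adjusted p = 0.120, in a range of 2.20e-05 to 0.120).

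The abundant miR-223-3p, miR-155-5p and miR-21a-5p, which rose with ConA, were not called in the main test of this comparison. miR-223-3p was at log2 -0.72 ± 0.23 (adjusted p = 0.106), miR-155-5p at -0.47 ± 0.23 (0.349) and miR-21a-5p at -0.03 ± 0.37 (0.990). Of the inflammation-induced list, 0 members were called by edgeR over all miRNAs or adjusted over the list alone, 0 had an unadjusted p under 0.05, and 0 were called by DESeq2 or limma-voom (camera, adjusted p = 0.732). In the other direction, 5 miRNAs with the smallest p-values did not pass: miR-99a-5p (1.76-fold higher, adjusted p = 0.0765), the endothelial miR-126a-3p (1.81-fold, 0.0795), miR-331-3p (2.91-fold, 0.0852), miR-99b-5p (1.84-fold, 0.0876) and miR-10a-5p (1.57-fold, 0.0876). DESeq2 called 4 of these 5, all but miR-331-3p, and the stellate cell miR-199a-3p higher, and all 5 were called without Vehicle replicate 1 (adjusted p = 0.0381, 0.0211, 0.0381, 0.0148 and 0.0381) or Vehicle replicate 2 (0.0282, 0.0129, 0.0282, 0.00674 and 0.0282). Adjusted over the list alone, both endothelial miRNAs were higher, as were 3 of 8 myeloid miRNAs, with 2 lower (camera for the myeloid list, adjusted p = 0.314).

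The miR-17~92 list did not pass (adjusted p = 0.314) but did without ConA+D8THC replicate 1 (0.0150, lower, in a range of 0.0150 to 0.968). The T cell activation (adjusted p = 0.766), miR-30 (0.766), bile duct epithelium (0.766), resting lymphocyte, let-7, lymphocyte, and stellate cell and fibroblast lists (each 0.920) did not pass in camera either. The sign of the test differed from the median log2 fold change for the let-7 (median -0.02), miR-30 (-0.06), lymphocyte (-0.02), and stellate cell and fibroblast (-0.49) lists. Neither miR-142a arm, the miR-34 family member nor the 2 Dlk1-Dio3 members were called.

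Opposite calls were counted to ask which miRNAs that differed with ConA differed the other way with D8THC. The 6 were miR-5121, miR-6538, miR-192-5p, miR-802-5p, miR-3535 and miR-194-5p, each higher in ConA+Vehicle than in both other groups. Of these, miR-192-5p, miR-802-5p and miR-194-5p are hepatocyte markers, and the others are entries listed as fragment-like. Against Vehicle, ConA+D8THC was lower for miR-802-5p (log2 -1.26, adjusted p = 0.0415) and miR-194-5p (-0.90, 0.0199) and higher for miR-6538 (2.86, 0.0164). The rest of the 6 were not called. The miR-802-5p call against Vehicle ended with library totals (0.0613). miR-192-5p averaged 3644, 10024 and 3077 CPM in Vehicle, ConA+Vehicle and ConA+D8THC, and miR-194-5p 2291, 4243 and 1227 CPM. miR-6538, from an intron of Rnf144a, averaged 5.02, 178 and 34.2 CPM. miR-3535, whose hairpin overlaps the small nucleolar RNA gene Gm24148 in Ncl, averaged 102, 395 and 157 CPM. Independent calls would give 2.19 such miRNAs, and the simulated unchanged groups gave a mean of 0.02 and at most 1. In these simulations ConA changed nothing either, so calls of any kind were rare by design. They do not show how many opposite calls would arise with the ConA changes kept and no effect of D8THC. Across all 297 miRNAs, the log2 fold changes of these comparisons had a Pearson's r of -0.47 and a covariance of -0.70, against -0.63 and -0.16 in simulations where only the shared libraries linked them; miRNAs are not independent replicates.

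The decrease of miR-3535 with D8THC (2.53-fold) was not called without ConA+Vehicle replicate 2 (adjusted p = 0.217), without ConA+D8THC replicate 1 (0.108), with library totals (0.0582) or with pancreas-enriched miRNAs left out (0.0671), in a range of 0.000570 to 0.217. That of miR-6538 (5.30-fold, adjusted p = 0.0382) ended only with the pancreas-enriched miRNAs left out (0.0611, in a range of 3.94e-08 to 0.0611), and was 3.52-fold without ConA+D8THC replicate 1 and 9.29-fold without ConA+D8THC replicate 2. The number of opposite calls was 13 in DESeq2, 14 with 2 against 2 libraries, and 4 with pancreas-enriched miRNAs left out. It was also 4 with fragment-like entries left out, which removed miR-5121, miR-6538 and miR-3535. Leaving out 1 library moved the number in either direction.

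**Figure D3:**
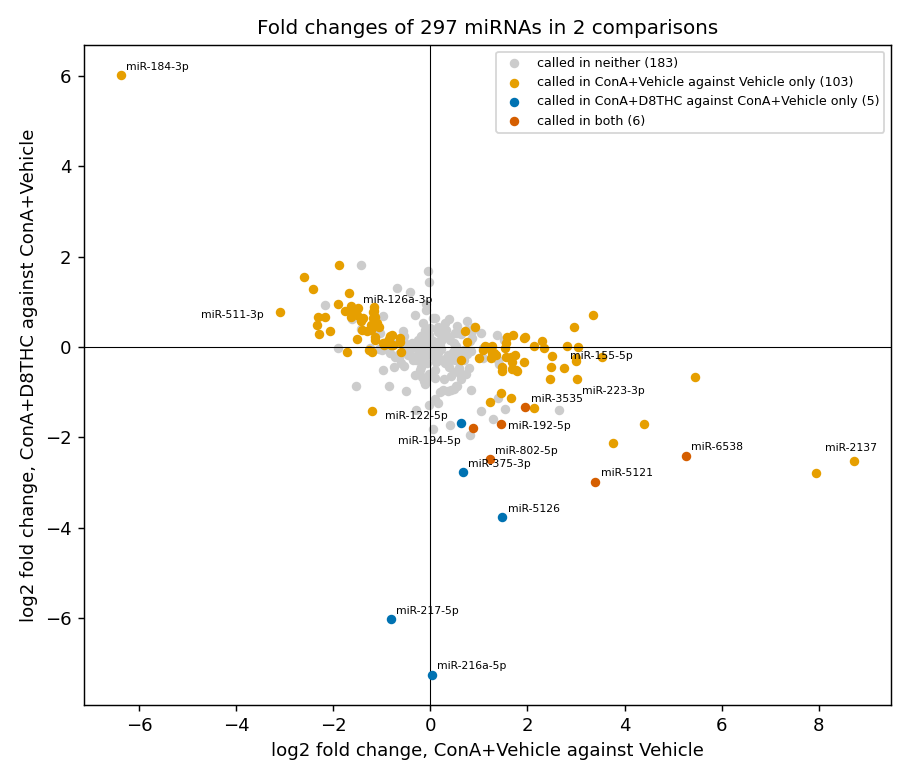
Log2 fold change of each of the 297 tested miRNAs in ConA+D8THC against ConA+Vehicle (vertical axis) and in ConA+Vehicle against Vehicle (horizontal axis), coloured by where it was called; the comparisons share the ConA+Vehicle libraries, and points with a group at 0 counts sit where the fit's prior count puts them. The 6 miRNAs called in both lie at the lower right, and 5 were called only in ConA+D8THC against ConA+Vehicle.

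ConA+D8THC was compared with Vehicle to ask what still differed from mice without disease. miR-223-3p was 4.93-fold higher, at 17331 ± 4190 CPM (SD, n = 2; log2 2.30 ± 0.24, adjusted p = 0.000164), and miR-155-5p 4.90-fold higher at 6372 ± 1290 CPM (adjusted p = 0.000164). miR-21a-3p was 10.4-fold higher (adjusted p = 0.000164) and miR-147-3p 9.96-fold. The hepatocyte strand miR-122-3p was 6.14-fold lower, at 28.2 ± 0.418 CPM against 173 ± 22.6 (adjusted p = 0.000439), and miR-216a-5p was at least 13.9-fold lower.

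In this comparison 97 miRNAs were called, 55 higher and 42 lower, all with groups that did not overlap; 222 of the 297 had such groups, against 33.3% expected by chance. Without ConA+D8THC replicate 1, 63 were called, 62 of them among the 97. Of these 97, 73 were also called in the same direction in ConA+Vehicle against Vehicle, where independent calls would give 18.0. Simulated unchanged groups sharing the Vehicle libraries gave a mean of 0.03 and at most 1, but there calls of any kind were rare by design. Pearson's r between the fold changes was 0.76 across miRNAs, against 0.42 in the simulations, and the covariance 1.54 against 0.09.

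The inflammation-induced list was higher (camera, adjusted p = 0.000851; adjusted p = 0.432 with an estimated correlation), with 8 of 11 members called higher, also adjusted over the list alone. miR-21a-5p was 2.84-fold higher (4.90-fold without Vehicle replicate 1). The miR-17~92 list was higher as well (camera, adjusted p = 1.27e-06; adjusted p = 0.432 with an estimated correlation), with 13 of 14 members called, also adjusted over the list alone; miR-93-5p was 2.44-fold and miR-25-3p 2.04-fold higher. miR-210-3p was 7.06-fold higher. The T cell activation list had 3 members higher and 1 lower of 9 (camera, adjusted p = 0.157, in a range of 0.00308 to 0.248). It was higher in fry (adjusted p = 0.00533). miR-142a-5p was 2.26-fold higher, or 3.60-fold without Vehicle replicate 1, and miR-142a-3p was not called in the main test (log2 0.75 ± 0.48). The Vehicle replicates differed in the share of counts of this pair, with 7.31% in replicate 1 and 2.53% in replicate 2.

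The share of counts from hepatocyte markers was 6.17% here and 11.1% in Vehicle. The hepatocyte list was lower (camera, adjusted p = 0.0483; adjusted p = 0.530 with an estimated correlation), with 4 of 6 members called lower, also adjusted over the list alone. It did not pass without Vehicle replicate 2 (0.106), without ConA+D8THC replicate 1 (0.102), with RLE factors (0.0531), with upper-quartile factors (0.0794) or with fragment-like entries left out (0.0648), in a range of 0.000607 to 0.106. miR-122-5p was 2.09-fold lower and miR-194-5p 1.87-fold lower. Both calls ended without Vehicle replicate 2 (adjusted p = 0.132 and 0.150) and without ConA+D8THC replicate 1 (0.129 and 0.0780); the lowest values over the alternatives were 2.20e-05 and 0.000106. miR-192-5p was not called (log2 -0.24 ± 0.28), nor was miR-148a-3p (0.01 ± 0.34).

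The endothelial miR-126a-3p was not called by edgeR, at 169366 ± 33822 CPM against 263518 ± 30228 (log2 -0.64 ± 0.24, adjusted p = 0.0615), but was by limma-voom (0.0463) and without Vehicle replicate 1 (0.0441); miR-126a-5p was at log2 -0.47 ± 0.27. Adjusted over the list alone, 1 of the 2 was lower. In the myeloid list 2 members were higher and 4 lower of 8 (camera, adjusted p = 0.592), with miR-511-3p 5.02-fold lower at 22.0 ± 0.964 CPM. miR-139-5p was 3.28-fold lower, miR-151-5p 3.61-fold, miR-652-3p 3.57-fold and miR-10a-5p 1.96-fold. The let-7 family had 4 of 10 lower (camera, adjusted p = 0.0644) and the miR-30 family 3 of 7 (0.157), with miR-30c-5p 2.50-fold lower. Both families were lower in fry (adjusted p = 0.0268 and 0.00533). The stellate cell and fibroblast list had 1 of 6 lower (camera, adjusted p = 0.0644), and passed without ConA+Vehicle replicate 1 (0.0362), ConA+Vehicle replicate 2 (0.0466) or ConA+D8THC replicate 2 (0.0142), in a range of 0.00308 to 0.208. The resting lymphocyte list had 1 member higher and 2 lower of 9 (0.659), and the lymphocyte list 1 of 6 higher (0.995; median log2 -0.15, mean 0.03), miR-342-3p, not called without ConA+D8THC replicate 1 (0.0543). edgeR called 0 members of the erythroid list (0.659), with 0 at an unadjusted p under 0.05 and 1 in DESeq2. It called 0 of bile duct epithelium (0.643), with 1 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom. The miR-34 family member and the 2 Dlk1-Dio3 members were not called.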

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

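Of the tests in this part, those with thinned libraries, without pancreas-enriched miRNAs and without fragment-like entries were chosen after the results were seen. Single named miRNAs were followed through up to 19 refits, not through thinning or changed thresholds. In these refits no called one changed direction, and those not called changed sign 169 times. With fragment-like entries left out, the larger group of calls turned from higher (59 against 50 lower) to lower (54 against 50 higher) in ConA+Vehicle against Vehicle, and from 55 higher and 42 lower to 51 and 54 in ConA+D8THC against Vehicle. The counts for ConA+Vehicle against Vehicle (109) and ConA+D8THC against Vehicle (97) stayed within 1.5 times under every alternative that kept all libraries, from 92 to 132 and from 74 to 133. With 1 library left out they ran from 67 (without ConA+Vehicle replicate 1) to 129 and from 63 (without ConA+D8THC replicate 1) to 112. The count for ConA+D8THC against ConA+Vehicle (11) and that of opposite calls (6) moved more. They were 17 and 10 with upper-quartile factors, 19 and 11 with no filter, 18 and 14 with a fit of 2 against 2 libraries, 17 and 13 in DESeq2, and 26 and 20 at an FDR of 0.1. Leaving out 1 library gave 8 to 40 and 4 to 25, where the lone library of a group is assumed to vary like the other groups. Leaving out either Vehicle library, which is in neither group of that comparison, raised the count to 34 or 40; the cause was not tested. With pancreas-enriched miRNAs left out it was 5, in part because 3 of the 11 were removed. The share of higher calls, 0% in that comparison, was 22.2% with 2 against 2 libraries, 27.3% with the replicate block, 29.4% in DESeq2, 30.8% at an FDR of 0.1, and 23.5%, 25% and 29.4% without Vehicle replicate 1, Vehicle replicate 2 and ConA+D8THC replicate 1. In ConA+D8THC against Vehicle, where it was 56.7%, it was 69.8% without ConA+D8THC replicate 1 and 68.9% with a 2-fold minimum. With libraries thinned to the smallest total, the counts were 97, 8.5 and 77 in the order of the comparisons, and 6.5 for opposite calls.

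The number of lists called was 2, 2 and 3 in that order. With an estimated correlation it was 0, 0 and 0; with fry, a test of a list on its own, 5, 0 and 5; with no filter 6, 3 and 7, when sparse miRNAs join the background. Leaving out 1 library gave 2 to 4, 1 to 3 and 2 to 4 lists. With erythroid and hepatocyte markers left out, 0 lists were called in ConA+D8THC against ConA+Vehicle, because both called lists were removed. Scaling moved the median log2 fold change of all miRNAs by over 0.1 in 4 cases: by -0.11 and 0.10 with RLE in the first and second comparisons, by -0.10 with upper-quartile factors in the second and by 0.10 with library totals in the third.

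Of 115 calls on single named miRNAs, 68 were kept in every refit (1 of them, miR-10a-5p in ConA+D8THC against Vehicle, under 2-fold) and 47 were lost in at least 1, 25 of these only when a library was left out. The replicate number as a block gave 132, 44 and 133 miRNAs, 32 opposite calls, and every miRNA called without it. The labels tie the numbers to no litter or batch, and replicate deviations of the groups correlated weakly across miRNAs (0.203, 0.238 and 0.0726), so the block was not used. An alternative planned for rows other than miRNAs gave no value, since the table holds mouse miRNAs alone. In simulations at these counts with 2 libraries per group, 34.2%, 32.5% and 38.5% of 2-fold changes in miRNAs that passed the filter were recovered.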

Other observations

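All tests in this part were chosen after the results were seen. Genomic clusters of tested miRNAs (13 clusters of at least 4 miRNAs with gaps under 10 kb, 65 one-sided Fisher's exact tests, 5 with an adjusted p under 0.05) were searched for shared changes. The 6 tested miRNAs placed in Mir17hg on chromosome 14 (115043671 to 115044391) were all higher in ConA+Vehicle and in ConA+D8THC than in Vehicle (adjusted p = 0.00162 for each). So were the 5 of the paralogous cluster on chromosome X from 52741693 to 52742567 (adjusted p = 0.00437 and 0.00405). Neighbours can share a transcript and paralogs can share reads, so cluster members are not independent and these p-values overstate the evidence. miR-92a-3p of the miR-17~92 list, named after its value was seen, was also higher in ConA+Vehicle (log2 1.74, adjusted p = 0.000379). The search by gene name assigned it to neither cluster, so the cluster tests left it out. This does not show that its hairpins lie elsewhere. miR-19b-3p has a hairpin in both clusters and counts in each, so they are not separate sets. Without ConA+Vehicle replicate 1, 4 of the 6 on chromosome 14 were higher in ConA+Vehicle (adjusted p = 0.0450). In Spaca6 on chromosome 17 (17830188 to 17830879), 4 of the 5 miRNAs of the miR-99b, let-7e and miR-125a cluster were lower in ConA+Vehicle than in Vehicle (adjusted p = 0.0412) and 2 of 5 in ConA+D8THC (adjusted p = 0.852). The first was 3 of 5 without Vehicle replicate 2 (adjusted p = 0.247), ConA+Vehicle replicate 1 (0.0648) or ConA+Vehicle replicate 2 (0.102) and in DESeq2 (0.302). The second was 4 without Vehicle replicate 1 (0.0262) and 0 without Vehicle replicate 2 or ConA+D8THC replicate 1 (adjusted p = 1 for each). In another cluster on chromosome X, 5 of 9 miRNAs were lower in ConA+Vehicle and 1 higher, and it did not pass (Fisher's exact test for lower, adjusted p = 0.0898). Its miR-351-5p was 3.72-fold lower, a call kept in 19 of 19 refits. The higher one, miR-503-5p, lost its call in 9 of 19 refits. The calls of miR-322-3p, miR-503-3p, miR-542-3p and miR-450b-3p were each lost in at least 1 refit. These 5 were named after their values were seen.

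Within hepatocyte miRNAs, miR-192-5p per 100 counts of miR-122-5p was 3.63 ± 0.438 in Vehicle, 6.34 ± 0.193 in ConA+Vehicle and 6.21 ± 0.535 in ConA+D8THC (SD, n = 2). Counts of miR-122-3p per 1000 of miR-122-5p were 1.76 ± 0.401, 0.494 ± 0.172 and 0.589 ± 0.128. miR-184-3p, named after its values were seen, had no count in ConA+Vehicle, at least 3.41-fold lower than Vehicle at 13.8 ± 7.78 CPM; its call ended without ConA+Vehicle replicate 1 (adjusted p = 0.0822, in a range of 0.00118 to 0.0822).

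Hepatocyte miRNAs were lower in ConA+D8THC than in ConA+Vehicle, by log2 -1.21 to -2.49. Thinning all libraries to the smallest total left the median log2 fold change at -1.72. Because thinning keeps each miRNA's expected share of a library, it could hardly move this value and does not test depth as a cause. A single hepatocyte RNA source present in different amounts may account for the decrease, but the test is weak. All 6 values were negative, which is the pattern that prompted it. The simulated draws with 1 common shift took the 6 as independent, while camera estimated a correlation of 0.691 among them, which would narrow their spread. That spread (Cochran's Q of 6.02) was reached in 39 of 100 such draws. The same spread was 44.5 in ConA+Vehicle against Vehicle and 39.1 in ConA+D8THC against Vehicle, each reached in 0 of 100 draws; the simulation replaced a large-sample form of this test, with the same outcome. Whether fewer hepatocytes, less released RNA or a response of hepatocytes to D8THC lies behind it stays open and untested; miR-192-5p and miR-194-5p are also abundant in gut epithelium.

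The acinar miRNAs miR-216a-5p and miR-217-5p had no count in ConA+D8THC, against 27 counts in ConA+Vehicle and 88 in Vehicle. Counting noise as the cause of this absence is argued against by the comparison with Vehicle, where the adjusted p over all tested miRNAs was at most 0.00204 for miR-216a-5p and 0.00246 for miR-217-5p under the alternatives; against ConA+Vehicle the highest were 0.0107 and, without ConA+Vehicle replicate 1, 0.0676. Pancreatic tissue carried into some livers could account for the pattern; the ratio of the pair over the 4 libraries that held them gave a Fisher's exact p of 0.580, but with as few as 4 counts this cannot be told apart from other sources. The islet miRNA miR-375-3p had 10 counts in ConA+D8THC and 78 elsewhere. A response of the mice to D8THC stays open and untested.

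Of 8 entries listed as fragment-like after their calls were seen, 7 were tested and 6 were called higher in ConA+Vehicle than in Vehicle, partly by that choice; together they took 0.0164% ± 0.000573 of counts in Vehicle, 0.315% ± 0.0254 in ConA+Vehicle and 0.0672% ± 0.0459 in ConA+D8THC (SD, n = 2). In ConA+D8THC against ConA+Vehicle, 4 of the 7 were called lower, also partly by that choice, beside 11 of all 297 tested. After thinning to the smallest total, 6 were still called higher in ConA+Vehicle than in Vehicle. Thinning keeps expected shares, and ConA+Vehicle already held the smallest libraries, so this says little about library depth as a cause. Of 8 tested miRNAs that overlap small nucleolar RNA genes, 2 were called higher (miR-5121 and miR-3535), beside 59 of all 297 tested. Whether reads from small nucleolar RNAs rose as a class cannot be told from this, since only reads assigned to mature miRNAs were counted. Fragments of ribosomal or other long RNAs, from dying cells or from handling, could still be a source; without a ribosomal reference or the reads this was not tested.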
